A study of Homo sapiens with 2 samples.

How the data were processed

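RNA was sequenced from 2 human leiomyosarcoma cell lines, SK-LMS-1 and SK-UT-1, each treated with the solvent DMSO and each represented by 1 library. Per the labels' protocols, total RNA was prepared with a stranded SMARTer total RNA kit from TaKaRa, so transcripts without a poly(A) tail can enter the libraries. The deposited table holds raw counts per gene, made by the authors with featureCounts 2.0.1 on the hg38 genome and a UCSC gene annotation, per the file headers. Its first line records counting of fragments over exons, grouped by gene name, with strand setting 1. The same line records that a fragment overlapping several genes was counted for each of them, and gives no option for counting reads that align to several places. Near-identical gene copies can therefore lose counts, and overlapping genes on 1 strand can share them. The aligner is not given in the sources used here. The table lists 26485 genes and no mitochondrial transcripts. It also holds 2 further columns of counts, which match neither sample and were not used here.

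Counts were used as deposited. They summed to 6906280 in SK-LMS-1 and 7635850 in SK-UT-1. CPM values (counts scaled to a common library size) were computed with edgeR 4.0.16 in R 4.3.3, with library sizes scaled by the trimmed mean of M values (TMM; factors 0.949 for SK-LMS-1 and 1.05 for SK-UT-1). A gene was called measured at 1 CPM or more in the higher library, which corresponds to 6.55 counts in SK-LMS-1 and 8.05 counts in SK-UT-1. Ratios were taken as SK-LMS-1 over SK-UT-1 on the log2 scale. A count below 3 was raised to 3 for the size rule, the ranking and the list medians. This floor equals 0.458 CPM in SK-LMS-1 and 0.373 CPM in SK-UT-1. A fold against a library at 0 counts is the ratio against that floor, written with at least. It is not a 95% limit. The lower end of the exact interval is smaller, for SERPINB2 3600 where the floor gives 4427. A fold against 1 to 3 counts is given as the ratio itself with its interval. Each ratio has an exact 95% interval from the conditional binomial (Clopper-Pearson) distribution, and shares of a library have exact Clopper-Pearson intervals. Intervals and floors cover counting error only and take the counted fragments as independent. Amplified reads without molecular identifiers are not independent molecules, so the intervals can be too narrow even for counting error.

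With 1 library per cell line there are no residual degrees of freedom, so no test between the lines was made, no p-value is given and no difference has a replicate check. The differences compare these 2 libraries. Before the data were examined, a 4-fold size rule was fixed for single genes, a 2-fold rule for members of gene lists, and 41 gene lists were written. A list was described by the median log2 ratio of its measured members and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. Lists with fewer than 3 measured members have no median. Percentiles describe these libraries and are not significance tests. Chromosome arms with at least 20 measured genes were described in the same way, with the table's hg38 coordinates and approximate centromere positions. The lists were matched to the table by symbol, 14 of the symbols through older names.

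The rule for naming genes was also fixed in advance. It took SUV39H1, SUV39H2, PARP1, PARP2, PARG and SLFN11, then the 10 largest ratios in each direction at 20 CPM or more. For each main list it took up to 2 members per direction, among those at least 2-fold different with 5 CPM or more. For each list of another cell type or of RNA quality it took the member with the highest CPM. Unnamed loci, pseudogenes, antisense and small RNA genes, and transcripts of X inactivation and of the Y chromosome, were left out. The rule named 124 genes, some of which are not reported here. Genes spread over several loci, and genes overlapping another on the same strand for over 20% of their exons, are marked as uncertain where they are named.

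The procedure was tested on simulated Poisson counts for 14050 genes, drawn from the means of the real libraries. Changed genes were picked at 5 CPM or more, and no variation beyond counting error was added. The simulation therefore checks the computation and not the error of comparing 1 library per line. All 100 genes changed 8-fold were called at 4-fold in the right direction (100%), none of the 100 genes changed 2-fold was called (0%), and 9 unchanged genes were called. The 95% interval held the true fold for 97.5% of the 200 changed genes. A list of 25 doubled genes had a median at percentile 100 and an unchanged list at percentile 64.5. Alternatives were other scalings (library totals, DESeq2 1.42.0 size factors, edgeR upper quartile), other filters, other size rules, a floor of 1 count, 10 expression bins, members with 10 counts in both libraries, and random thinning of the deeper library. Against TMM, library totals moved the median log2 ratio of all measured genes by -0.15, the upper quartile by -0.13 and DESeq2 by -0.0012. GC content and sequence uniqueness came from reference transcripts. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.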

Results

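Gene expression was measured by total RNA sequencing in 2 human leiomyosarcoma cell lines, tumours of smooth muscle origin, under the solvent DMSO. SK-LMS-1 and SK-UT-1 were each represented by 1 library. The series concerns the combined use of an inhibitor of SUV39H2, an enzyme that methylates lysine 9 of histone H3 (H3K9), with an inhibitor of poly(ADP-ribose) polymerases (PARP) in uterine leiomyosarcoma. The comparison made here asks how the lines differed with solvent alone. The libraries held 6906280 counts for SK-LMS-1 and 7635850 for SK-UT-1, with 16383 and 16741 genes at 1 count or more and 12672 and 12755 genes at 10 or more. No difference below has a replicate check, because each line has 1 library. Expression is given in TMM-scaled CPM. The range in parentheses after a fold is its exact 95% interval, which covers only the counting error of fragments taken as independent.

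The make-up of the libraries was similar for protein-coding classes and differed for abundant non-coding RNAs. Ribosomal protein genes took 2.13% of counts in SK-LMS-1 (exact 95% interval 2.12 to 2.14) and 2.14% in SK-UT-1 (2.13 to 2.15). The replication-dependent histone genes, whose transcripts lack a poly(A) tail, took 0.217% (0.213 to 0.220) and 0.232% (0.229 to 0.236). RN7SK, the small nuclear RNA that holds back transcription elongation, took 1.05% (1.04 to 1.06) in SK-LMS-1 and 0.544% (0.538 to 0.549) in SK-UT-1. MALAT1, a nuclear long non-coding RNA, took 0.258% (0.254 to 0.262) and 0.605% (0.599 to 0.610). The 10 most abundant genes of each library held 4.92% (4.91 to 4.94) and 4.61% (4.60 to 4.63) of its counts. With small RNA genes left out of the top 10 and of the total, an alternative chosen after seeing the data, the shares were 4.19% and 4.41%, so the larger share in SK-LMS-1 rests on RN7SK.

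Genes of the extracellular matrix and of protease control led the differences towards SK-LMS-1. SERPINB2, an inhibitor of plasminogen activators, reached 1650 CPM in SK-LMS-1 and 0 counts in SK-UT-1, at least 4427-fold higher against the floor (lower 95% limit 3600). FN1, which encodes fibronectin, stood at 2069 against 0.745 CPM, 2775-fold higher (1275 to 7564). SERPINB7 was at least 2248-fold higher, the collagenase MMP1 at least 1408-fold, the matrix proteoglycan gene VCAN at least 1406-fold, the cytokine receptor gene IL7R at least 871-fold, the stromelysin MMP3 at least 816-fold and the microfibril gene FBN2 at least 770.2-fold. DSEL, listed over several loci and thus uncertain, was 1055-fold higher (361 to 5120) against 3 counts in SK-UT-1.

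In the other direction, ALDH1A1, an aldehyde dehydrogenase that makes retinoic acid, reached 3204 CPM in SK-UT-1 against 0.763 CPM in SK-LMS-1, 4198-fold higher (1799 to 12931). PTPRZ1, a receptor tyrosine phosphatase, was 1559-fold higher in SK-UT-1 (279 to 61610) and TES, a focal adhesion protein, 733-fold (131 to 28972), each against 1 count. The matrix gene FBLN2 was 332-fold higher (113 to 1613), the scaffold gene MPDZ 309-fold (120.3 to 1135) and the transcription factor gene DACH1 198-fold (67.5 to 963). Of genes at 0 counts in SK-LMS-1, the neuronal kinesin KIF1A was at least 281-fold higher in SK-UT-1, QPCT at least 201-fold, the growth factor gene BMP5 at least 199-fold and the helicase gene DDX43 at least 177-fold.

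Among 14324 measured genes, 1639 were at least 4-fold higher in SK-LMS-1 and 1046 in SK-UT-1, together 18.7%. Of these, 501 and 339 had 0 counts in the other line. Another 8566 genes (59.8%) lay within 2-fold. Across genes, which are not independent replicates, the libraries correlated with Pearson's r of 0.759 on log2(CPM + 0.5) and Spearman's rho of 0.808. The count for SK-UT-1 was 656 at 5 CPM or more and 606 where the whole interval had to lie beyond 4-fold.

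**Figure D1:**
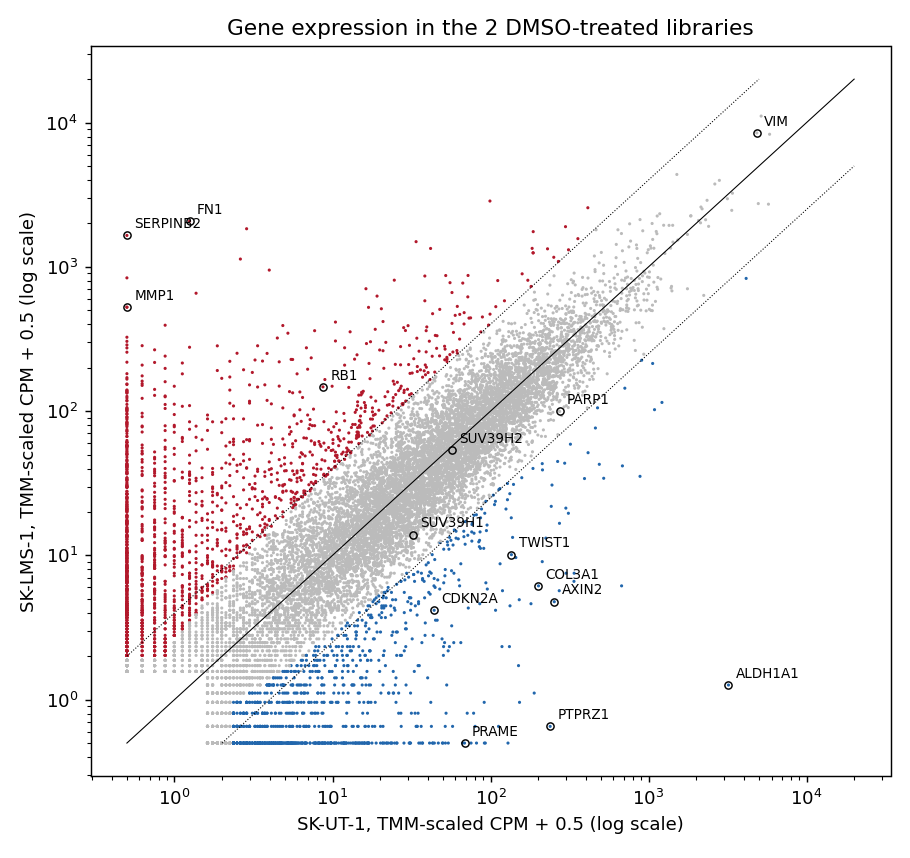
Each point is a measured gene, with TMM-scaled CPM + 0.5 in SK-UT-1 on the x axis and in SK-LMS-1 on the y axis, both on log scales; the solid line marks equality and the dotted lines a 4-fold difference. Red points are the 1639 genes at least 4-fold higher in SK-LMS-1, blue points the 1046 at least 4-fold higher in SK-UT-1 and grey points the rest, with SUV39H2 close to the line of equality and FN1 and ALDH1A1 at opposite corners.

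SUV39H2, the enzyme named in the study's title, differed little between the lines. It stood at 53.3 CPM in SK-LMS-1 and 56.3 CPM in SK-UT-1, 1.06-fold higher in SK-UT-1 (0.917 to 1.22), not a detectable difference with TMM scaling. The log2 interval excluded 0 when scaled by library totals (-0.44 to -0.03) or by the upper quartile (-0.42 to -0.01). SUV39H1, its close relative, was 2.36-fold higher in SK-UT-1 (1.84 to 3.04), at 31.7 against 13.4 CPM. FAM208A, now called TASOR and the scaffold of a complex that silences repeats through H3K9 methylation, was 2.66-fold higher in SK-LMS-1 (2.43 to 2.91), at 234 against 88.2 CPM. SUV39H1 and FAM208A were the only members of the 24-gene H3K9 methylation list that differed by 2-fold or more, and the other 22 lay within 2-fold. The list median of -0.41 (log2, SK-LMS-1 over SK-UT-1) lay at percentile 1.07 of matched random lists. The list pools enzymes that add H3K9 methylation, enzymes that remove it and other proteins. Its median therefore gives no direction for the methylation itself. Scaled by library totals, 2 members were at least 2-fold higher in SK-UT-1. In hg38, SUV39H2 spans chromosome 10, 14878783 to 14904305, and SUV39H1 spans chromosome X, 48695554 to 48709015, both on the plus strand.

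PARP1, the main target of PARP inhibitors, was 2.77-fold higher in SK-UT-1 (2.53 to 3.02), at 273 against 98.9 CPM. PARP2, which shares its role in repair of strand breaks, stood at 52.3 CPM in SK-LMS-1 and 57.0 CPM in SK-UT-1, 1.09-fold higher in SK-UT-1 (0.945 to 1.26), not a detectable difference with TMM scaling. Its log2 interval also excluded 0 with library totals (-0.48 to -0.07) and with the upper quartile (-0.46 to -0.05). PARG, which removes poly(ADP-ribose) chains, was 1.32-fold higher in SK-UT-1 (1.14 to 1.53), at 59.6 against 45.3 CPM. Other members went the opposite way. TIPARP, a target gene of the aryl hydrocarbon receptor, was 43.3-fold higher in SK-LMS-1 (32.8 to 58.3), and PARP8 77.0-fold (25.9 to 377) against 3 counts. PARP10 was 3.82-fold higher in SK-UT-1 (2.49 to 6.08). The PARP family list also holds PARG and other genes that do not encode polymerases. Of its 20 members, 5 were at least 2-fold higher in SK-LMS-1, 2 in SK-UT-1 and 13 lay within 2-fold. The median of 0.44 lay inside the random range at percentile 95.7. PARP1 lies on the minus strand of chromosome 1, 226360691 to 226408100, PARP2 on the plus strand of chromosome 14, 20343614 to 20357904, and PARG on the minus strand of chromosome 10, 49818275 to 49942027.

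SLFN11, a gene whose expression is known to go with sensitivity to PARP inhibitors, was 1.41-fold higher in SK-LMS-1 (1.24 to 1.60), at 79.5 against 56.5 CPM. It lies on the minus strand of chromosome 17, 35350310 to 35373701. ABCG2, a drug efflux transporter, was 66.3-fold higher in SK-LMS-1 (17.9 to 555), with 108 against 2 counts. CHD1L, a chromatin remodeller recruited by poly(ADP-ribose), was 2.06-fold higher in SK-UT-1 (1.77 to 2.42). Of 19 measured genes of the PARP inhibitor response list, 2 were at least 2-fold higher in SK-LMS-1, 1 in SK-UT-1 and 16 lay within 2-fold. Its median of 0.10 lay at percentile 63.4 and was below 0 when scaled by library totals or the upper quartile.

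Most DNA repair genes lay within 2-fold. In the homologous recombination list, the nuclease gene EXO1 was 2.97-fold higher in SK-UT-1 (2.61 to 3.39) and the helicase gene BLM 2.41-fold (2.12 to 2.75). The end resection genes MRE11A and RBBP8 were higher in SK-LMS-1, by 2.24-fold (1.99 to 2.52) and 2.09-fold (1.89 to 2.31). Of its 25 members, 2 were at least 2-fold higher in SK-LMS-1, 3 in SK-UT-1 and 20 lay within 2-fold, with a median of -0.40 at percentile 1.78. With the deeper library thinned, that median was -0.34 at percentile 3.96, inside the random range, and under library totals 1 and 5 members passed 2-fold. FANCA, of the core complex that handles DNA crosslinks, was 2.81-fold higher in SK-UT-1 (2.36 to 3.36), while the other 12 Fanconi anaemia genes lay within 2-fold (median -0.28, percentile 17.5). In end joining, XRCC4 was 2.19-fold higher in SK-LMS-1 (1.67 to 2.88) and C9orf142, now called PAXX, 2.85-fold higher in SK-UT-1 (1.79 to 4.69), and 12 of 14 measured genes lay within 2-fold (median -0.05, percentile 38.8).

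In the mismatch repair list, 1 of 7 genes was at least 2-fold higher in SK-LMS-1 and 6 lay within 2-fold, with a median of 0.21 at percentile 71.3. Base excision repair held 3 genes at least 2-fold higher in SK-UT-1, 13 within 2-fold and 0 higher in SK-LMS-1, with a median of -0.50 at percentile 2.98, just inside the random range. The glycosylase genes NEIL3 and TDG were 3.30-fold (2.63 to 4.17) and 2.75-fold (2.26 to 3.37) higher in SK-UT-1. CHEK2, a checkpoint kinase, was 2.23-fold higher in SK-UT-1 (1.78 to 2.82) and was the 1 gene of the 14-gene damage checkpoint list that differed by 2-fold (median -0.22, percentile 17.4).

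The medians of the cell cycle lists were higher in SK-UT-1, while most members lay within 2-fold. CCNE1, the cyclin that drives entry into S phase, was 4.39-fold higher in SK-UT-1 (3.35 to 5.84), and SLBP, which binds histone mRNA, 2.72-fold (2.47 to 2.99). TOP2A stood at 1762 against 704 CPM, 2.5-fold higher (2.42 to 2.59), and the mitotic kinase gene PLK1 was 2.41-fold higher (2.20 to 2.64). In the G1/S replication list, 3 of 23 genes were at least 2-fold higher in SK-UT-1 and 20 lay within 2-fold. In the G2/M list these counts were 4 and 16 of 20. Neither list had a member at least 2-fold higher in SK-LMS-1. The medians of -0.57 and -0.60 both lay at percentile 0.04. Scaled by library totals, 6 G1/S genes passed 2-fold.

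Smooth muscle genes were split between the lines. MYLK, the myosin light chain kinase of contraction, was 41.6-fold higher in SK-LMS-1 (33.3 to 52.6), at 414 against 9.94 CPM. ACTG2, the enteric smooth muscle actin, was at least 16-fold higher in SK-LMS-1, from a low level of 5.95 CPM. ACTA2, the vascular smooth muscle actin, was 5.13-fold higher in SK-UT-1 (3.97 to 6.72), at 54.0 against 10.5 CPM. Of 19 measured genes, 8 were at least 2-fold higher in SK-LMS-1, 3 in SK-UT-1 and 8 lay within 2-fold, with a median of 0.36 at percentile 88.1.

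Mesenchymal genes were mostly higher in SK-LMS-1, with exceptions among transcription factors. FN1 had the largest ratio of that list, and PRRX1, a mesenchymal homeobox gene, was 278-fold higher (94.9 to 1353) against 3 counts in SK-UT-1. TWIST1 and SNAI2, transcription factors of epithelial-mesenchymal transition, were 14-fold (10.9 to 18.4) and 2.20-fold (1.96 to 2.46) higher in SK-UT-1. Of 16 measured members, 10 were at least 2-fold higher in SK-LMS-1, 2 in SK-UT-1 and 4 lay within 2-fold (median 2.48, percentile 100). VIM, the intermediate filament vimentin, named outside the rule after its values were seen, was abundant in both lines at 8473 and 4844 CPM. Epithelial genes were split. The keratin genes KRT7 and KRT18 were 211-fold (71.8 to 1026) and 6.94-fold (5.50 to 8.84) higher in SK-LMS-1. The junction gene JUP and the protease inhibitor gene SPINT1 were at least 75.7-fold and at least 35.8-fold higher in SK-UT-1. Of 15 measured epithelial genes, 6 were at least 2-fold higher in SK-LMS-1, 7 in SK-UT-1 and 2 lay within 2-fold (median -0.96, percentile 7.67). At 5 CPM or more that median was -1.49 at percentile 2.38, and over members with 10 counts in both libraries -0.47 at percentile 20.9.

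Matrix genes were mostly higher in SK-LMS-1. TNC, encoding tenascin, was 273-fold higher in SK-LMS-1 (189 to 411), at 949 against 3.48 CPM. COL3A1, a fibrillar collagen, was 35.5-fold higher in SK-UT-1 (25.7 to 50.7) and FBLN1 68.5-fold (29.1 to 212). The collagens and matrix list had 15 of 26 measured members at least 2-fold higher in SK-LMS-1, 3 in SK-UT-1 and 8 within 2-fold, with a median of 2.01 at percentile 100. Among matrix proteases and their inhibitors, 14 of 18 were at least 2-fold higher in SK-LMS-1, 2 in SK-UT-1 and 2 within 2-fold (median 2.21, percentile 100). TIMP3, an inhibitor of metalloproteinases, was 2.27-fold higher in SK-UT-1 (1.78 to 2.92). Restricting members to 10 counts or more in both libraries, which leaves out the genes silent in 1 line, gave medians of 0.81 for the mesenchymal and 0.75 for the matrix list.

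**Figure D2:**
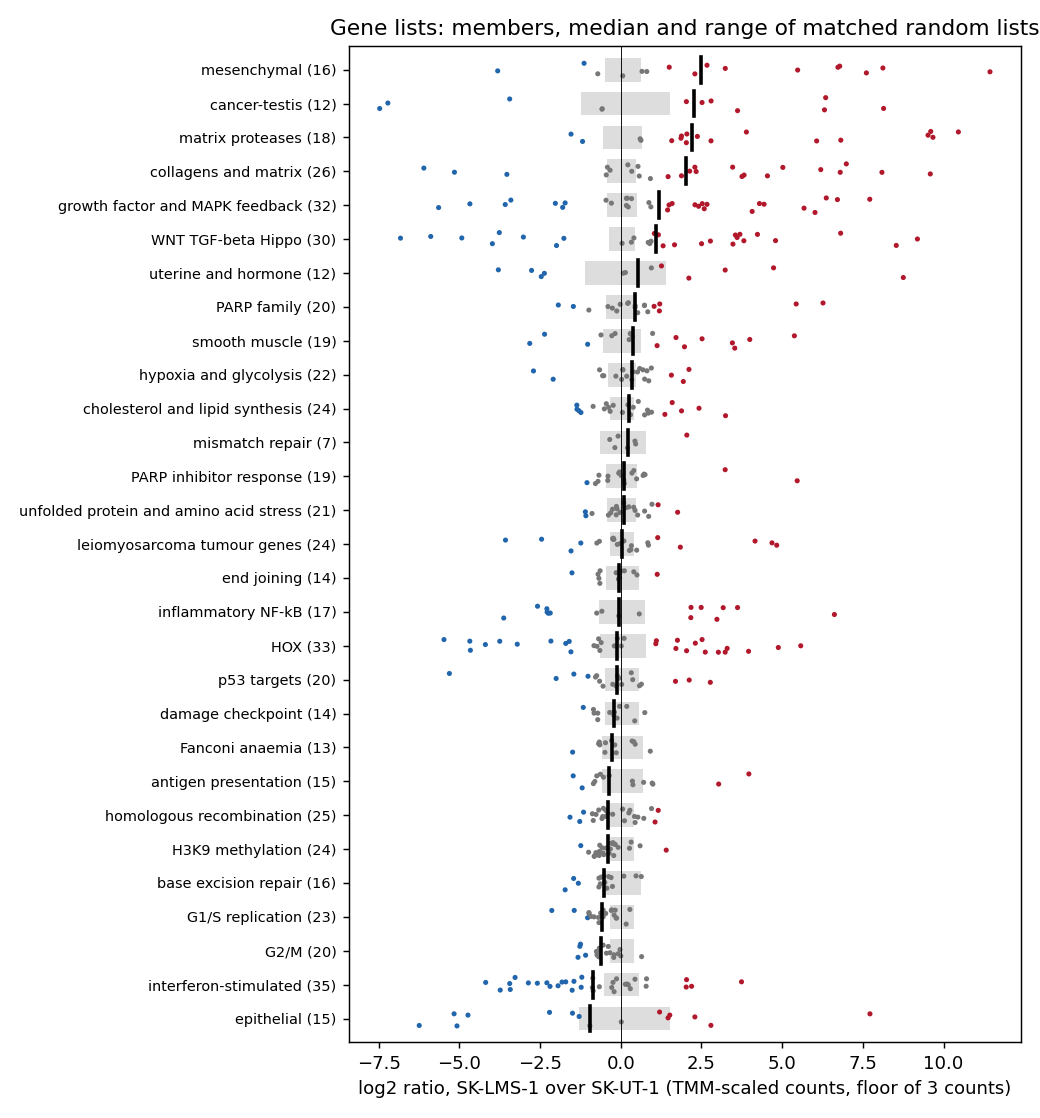
Each row is a gene list with its number of measured genes in parentheses, and each point a member's log2 ratio of SK-LMS-1 over SK-UT-1, red where at least 2-fold higher in SK-LMS-1, blue where at least 2-fold higher in SK-UT-1 and grey otherwise. Black bars are list medians and grey boxes hold 95% of the medians of 10000 matched random lists; the mesenchymal median of 2.48 lies right of its box and the interferon-stimulated median of -0.87 left of its box.

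FOXA2, a transcription factor of uterine glands, was at least 26.6-fold higher in SK-LMS-1, at 9.92 CPM. FOXL2, a gonadal transcription factor, was 41.5-fold higher in SK-UT-1 (7.12 to 1672), and the nuclear receptor gene NR2F1 5.51-fold (4.82 to 6.31). The uterine and hormone list held 5 of 12 measured genes at least 2-fold higher in SK-LMS-1, 4 in SK-UT-1 and 3 within 2-fold (median 0.55, percentile 80.7). HOX genes, which set position along the body axis, went both ways. HOXA9 and HOXD10 were 47.7-fold (21.6 to 131) and 29.5-fold (9.69 to 146) higher in SK-LMS-1, the first uncertain because it overlaps a gene on its strand. HOXC13 and HOXB9 were 134-fold (23.6 to 5305) and 25.6-fold (14.8 to 48.4) higher in SK-UT-1. Of 33 measured HOX genes, 14 were at least 2-fold higher in SK-LMS-1, 10 in SK-UT-1 and 9 lay within 2-fold, with a median of -0.10 at percentile 36.1 and a mean of 0.07. At 5 CPM or more the HOX median was -0.63 at percentile 1.66.

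Growth factor and MAPK feedback genes had a higher median in SK-LMS-1, with members in both directions. ETV1, a transcription factor downstream of MAPK signalling, was 630.1-fold higher in SK-LMS-1 (113 to 24937) against 1 count, and DUSP4, a phosphatase that dampens the pathway, 105-fold (44.6 to 325). The receptor genes FGFR4 and FGFR3 were at least 49.9-fold and 76.5-fold (13.4 to 3054) higher in SK-UT-1. Of 32 measured members, 16 were at least 2-fold higher in SK-LMS-1, 7 in SK-UT-1 and 9 within 2-fold (median 1.19, percentile 100). The list of WNT, TGF-beta and Hippo genes had 16 of 30 at least 2-fold higher in SK-LMS-1, 8 in SK-UT-1 and 6 within 2-fold (median 1.10, percentile 100). INHBA, a subunit of activin, was at least 584-fold higher in SK-LMS-1, and GREM1, a secreted BMP antagonist listed over several loci and thus uncertain, at least 371-fold. AXIN2, a target gene of WNT signalling, was 59.1-fold higher in SK-UT-1 (40.8 to 89.2), at 253 against 4.27 CPM. TCF7L1, a transcription factor of that pathway, was 169.7-fold higher in SK-UT-1 (46.7 to 1406).

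Interferon-stimulated genes had a lower median in SK-LMS-1, with members in both directions. OAS1, a sensor of double-stranded RNA, was 18.2-fold higher in SK-UT-1 (5.96 to 90.4) and IFITM1, a membrane protein that blocks virus entry, 13.3-fold (4.29 to 66.7), each from 3 counts in SK-LMS-1. IFI44 and IFI44L, neighbours on chromosome 1, were 13.4-fold (6.76 to 30.1) and 4.58-fold (2.31 to 9.88) higher in SK-LMS-1. Of 35 measured genes, 16 were at least 2-fold higher in SK-UT-1, 4 in SK-LMS-1 and 15 lay within 2-fold, with a median of -0.87 at percentile 0.05. Over members with 10 counts or more in both libraries the median was -0.28 at percentile 12.3, inside the random range.

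In antigen presentation, HLA-B was 2.29-fold higher in SK-UT-1 (2.04 to 2.57), and HLA-DPA1 15.7-fold (5.76 to 59.7) higher in SK-LMS-1. Both are uncertain, since the table lists them over several loci. Of 15 measured genes, 2 were at least 2-fold higher in each line and 11 lay within 2-fold, with a median of -0.36 at percentile 10 and a mean of opposite sign at 0.26. Inflammatory genes were split by gene. PTGS2, the inducible cyclooxygenase, was at least 98.3-fold higher in SK-LMS-1, and CXCL8 9.02-fold (6.79 to 12.2). CXCL5 and CXCL3, chemokines of the same family, were 12.3-fold (7.05 to 23.6) and 5.97-fold (3.47 to 11) higher in SK-UT-1. The inflammatory list had 7 of 17 genes at least 2-fold higher in SK-LMS-1, 6 in SK-UT-1 and 4 within 2-fold (median -0.06, percentile 43.4, mean 0.42).

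Tumour genes of leiomyosarcoma differed strongly as single genes. CDK6, a kinase of the G1 phase, stood at 512 against 19.9 CPM, 25.7-fold higher in SK-LMS-1 (22 to 30.3), and the chromatin protein gene HMGA1 was 28.5-fold higher (23.3 to 35.2). CDKN2A, an inhibitor of that kinase, was 11.9-fold higher in SK-UT-1 (7.85 to 18.8) and NF1, a negative regulator of RAS, 5.47-fold (4.91 to 6.11). Of the list's 24 genes, 5 were at least 2-fold higher in SK-LMS-1, 4 in SK-UT-1 and 15 within 2-fold. Its median of 0.04 lay at percentile 58.9 and was below 0 under scaling by library totals or the upper quartile. Among p53 target genes, CDKN1A, which arrests the cell cycle, was 6.84-fold (4.76 to 10.1) and PLK3 4.35-fold (2.74 to 7.16) higher in SK-LMS-1. BTG2 was 39.6-fold (13.3 to 194) and the death receptor gene FAS 4.0-fold (3.41 to 4.72) higher in SK-UT-1. Of 20 measured targets, 3 were at least 2-fold higher in SK-LMS-1, 4 in SK-UT-1 and 13 within 2-fold (median -0.12, percentile 31.7).

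Genes of the cancer-testis list, many but not all of them normally restricted to the germ line, were detected as different members in each line. MAGEC2 stood at 105 CPM in SK-LMS-1 and 0 counts in SK-UT-1, at least 283-fold higher, and MAGEC1 was at least 81.5-fold higher. PRAME, listed over several loci and thus uncertain, stood at 68.0 CPM in SK-UT-1 and 0 counts in SK-LMS-1, at least 148-fold higher. DDX43 was also higher in SK-UT-1. Of the 37 genes listed, 12 were measured, 7 of them at least 2-fold higher in SK-LMS-1, 3 in SK-UT-1 and 2 within 2-fold (median 2.28, percentile 99.8). At 5 CPM or more the median reversed to -0.57 at percentile 13.4.

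Metabolic and stress genes differed in single members more than as lists. The fatty acid elongase ELOVL6 was 5.37-fold higher in SK-LMS-1 (4.61 to 6.28). ACLY and SREBF1, of fatty acid synthesis and its control, were 2.57-fold (2.40 to 2.75) and 2.56-fold (2.14 to 3.07) higher in SK-UT-1. The cholesterol and lipid synthesis list had 5 of 24 genes at least 2-fold higher in SK-LMS-1, 4 in SK-UT-1 and 15 within 2-fold (median 0.26, percentile 89.0). In hypoxia and glycolysis, NDRG1 and VEGFA, the vascular growth factor, were 4.33-fold (3.29 to 5.76) and 3.83-fold (3.40 to 4.33) higher in SK-LMS-1, and ALDOC and ADM 6.51-fold (3.56 to 13) and 4.26-fold (3.54 to 5.17) higher in SK-UT-1. Of 22 measured genes, 3 and 2 were at least 2-fold higher in SK-LMS-1 and SK-UT-1, and 17 lay within 2-fold (median 0.36, percentile 94). ERN1, a sensor of unfolded protein, and VLDLR were 3.39-fold (2.53 to 4.60) and 2.23-fold (1.74 to 2.86) higher in SK-LMS-1. TRIB3 and PHGDH, the first enzyme of serine synthesis, were 2.14-fold (1.47 to 3.16) and 2.11-fold (1.87 to 2.39) higher in SK-UT-1. The other 17 of 21 unfolded protein and amino acid stress genes lay within 2-fold, and that median of 0.09 at percentile 65.5 was below 0 under scaling by library totals or the upper quartile.

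Markers of other cell types were sparse. Of 18 immune markers 2 were measured, 1 at least 2-fold higher in each line, and CD68, a lysosomal protein of macrophages also made by other cells, was 6.32-fold higher in SK-LMS-1 (5.18 to 7.77). No erythroid gene was measured (0 of 12). Endothelial markers had 6 measured, 3 higher in each line (median -0.26, percentile 39.6), and TIE1, an endothelial receptor kinase, was at least 97.9-fold higher in SK-LMS-1. TUBB3, a tubulin of neurons, was 6.0-fold higher in SK-UT-1 (5.30 to 6.80). Of 9 measured neural markers, 4 were at least 2-fold higher in SK-LMS-1, 2 in SK-UT-1 and 3 within 2-fold (median 0.32, percentile 76.1). Over neural markers with 10 counts in both libraries the median was -0.60. Of 3 measured skeletal muscle genes, 2 were at least 2-fold higher in SK-UT-1 (median -2.52, percentile 3.86), with TNNT1 at 5.72-fold (4.13 to 8.10). Squamous markers gave the same counts (median -1.93, percentile 6.72), and KRT10 was 1.75-fold higher in SK-UT-1 (1.14 to 2.73). Adipose and cartilage markers had 5 of 6 measured genes at least 2-fold higher in SK-LMS-1 and 1 in SK-UT-1 (median 3.29, percentile 99.7), with RUNX2, the transcription factor of bone formation, 4.24-fold higher in SK-LMS-1 (3.67 to 4.90).

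Immediate early and heat shock genes had 8 of 19 members at least 2-fold higher in SK-LMS-1, 1 in SK-UT-1 and 10 within 2-fold (median 0.61, percentile 94.3), and the abundant chaperone HSPA8 was 1.23-fold higher in SK-LMS-1 (1.21 to 1.26). Ribosomal protein genes had 76 of 82 within 2-fold, 4 higher in SK-LMS-1 and 2 in SK-UT-1 (median 0.19, percentile 96.3). RPL4, with the highest CPM among them, was 1.06-fold higher in SK-UT-1 (1.04 to 1.08). Histone genes were split, with 28 of 65 at least 2-fold higher in SK-LMS-1, 18 in SK-UT-1 and 19 within 2-fold. The 65 and the 18 include 3 pairs of HIST2 genes with the same coordinates and counts, so each pair is the same measurement listed under both names. The histone median of 0.15 at percentile 74.8 was below 0 under library totals and over members with 10 counts in both libraries. HIST1H2BC was 2.98-fold higher in SK-UT-1 (2.76 to 3.22), at 381 against 128 CPM. The table lists 0 mitochondrial transcripts.

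Zinc finger genes of the ZNF family, many of which lie in domains marked by H3K9 trimethylation, were lower as a family in SK-LMS-1. Of 494 measured genes, 106 were at least 2-fold higher in SK-UT-1, 54 in SK-LMS-1 and 334 lay within 2-fold. The median of -0.38 lay at percentile 0 of matched random lists, whose central 95% ran from -0.11 to 0.12. ZNF711 was at least 67.0-fold higher in SK-UT-1 and ZNF608 71.6-fold (40.8 to 139). ZNF804A was at least 65.1-fold higher in SK-LMS-1, and ZNF486 402-fold (71.6 to 15913) against 1 count.

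Across the 38 lists with a median, 7 lay above and 6 below the central 95% of their random lists, 13 in all. Independent lists of unrelated genes would give about 1.9. Members of a list can vary together and some genes sit on several lists, so 1.9 is a reference and not a test.

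Whole chromosome arms also differed. Genes on Xq had a median log2 ratio of 1.04 (309 genes), on 6q 0.70 (312 genes), on 7p 0.62 (239 genes), on 20p 0.57 (130 genes) and on 7q 0.52 (457 genes), all higher in SK-LMS-1. Genes on 1q had a median of -0.68 (601 genes), on 16p -0.63 (305 genes), on 22q -0.54 (328 genes) and on 16q -0.52 (278 genes), all higher in SK-UT-1. PARP1 lies on 1q. Of 41 arms, 15 lay above and 10 below the central 95% of matched random lists, 25 in all. Independently drawn genes would give about 2.05, again a reference and not a test. The medians of 5q and 12q, 0.15 and 0.12, were below 0 under other scalings but stayed above the random range made with those scalings.

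**Figure D3:**
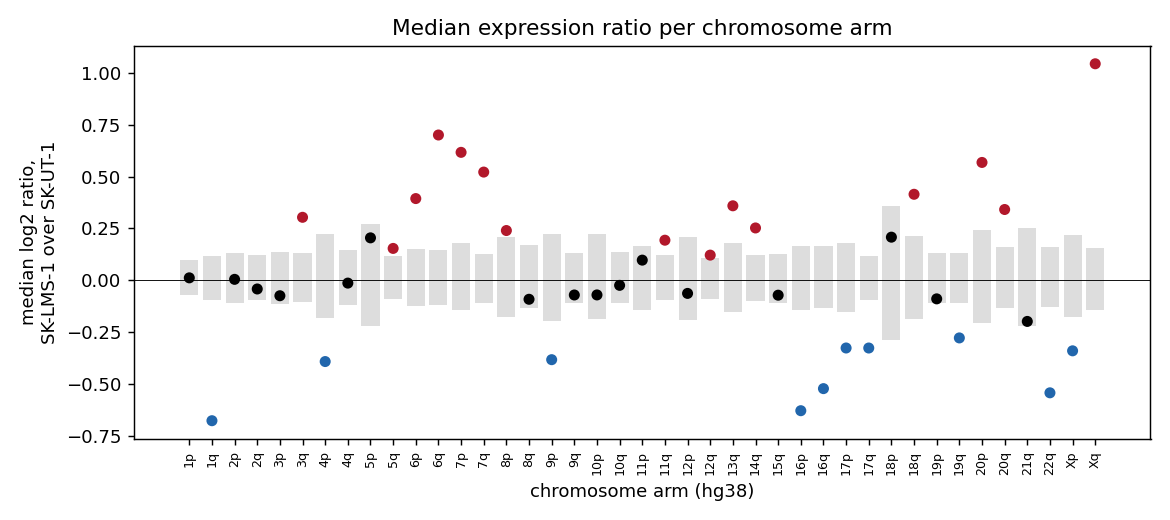
Each point is the median log2 ratio of SK-LMS-1 over SK-UT-1 for the measured genes of a chromosome arm (x axis), red above, blue below and black inside the grey bar that holds 95% of the medians of 10000 random gene lists of the same size and expression. The largest departures in each direction are Xq at 1.04 and 1q at -0.68.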

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

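No paired analysis was possible because each cell line has 1 library. No alternative reversed the direction of a named gene. Of the 13 lists outside their random range, 10 were outside it under every alternative that gave a value and 12 kept their side. The adipose and cartilage list, among the 10, and the cancer-testis list gave none over members with 10 counts in both libraries. Homologous recombination was inside with the deeper library thinned to the total of the shallower (-0.34), interferon-stimulated genes were inside over members with 10 counts in both libraries (-0.28), and the cancer-testis median reversed to -0.57 at 5 CPM or more, where fewer genes enter. Medians that moved by over 1.5 times while staying inside or outside the random range as reported included, at 5 CPM or more, uterine and hormone genes (1.26), inflammatory genes (-0.40) and endothelial markers (-1.40), under library totals antigen presentation (-0.60) and adipose and cartilage markers (1.93), with a floor of 1 count cancer-testis genes (3.86), and over members with 10 counts in both libraries immediate early genes (0.30), mesenchymal genes (0.81) and matrix genes (0.75). All 25 arms outside their random range stayed outside on the same side under the alternatives run for arms (the other scalings, thinning, and 5 CPM or more), although 5q had a median of -0.0070 under library totals and 12q one of -0.036 under library totals and -0.018 under the upper quartile, both scalings that move all genes down. Genes higher in SK-LMS-1 numbered 3140 at 2-fold and 977 at 8-fold. Genes higher in SK-UT-1 numbered 2618 at 2-fold, 511 at 8-fold, 656 at 5 CPM or more and 606 with the whole interval beyond 4-fold. Under the other alternatives both counts stayed within 1.5 times the reported ones. With small RNA genes left out of the denominator alone, the 10 most abundant genes held 4.99% of counts in SK-LMS-1 and 4.66% in SK-UT-1. With these genes left out of the top 10 as well, an alternative chosen after seeing the data, the shares were 4.19% and 4.41%, since RN7SK, in both top 10 sets, took 72677 counts in SK-LMS-1 and 41505 in SK-UT-1. Depth limits low genes most: a gene at 1 CPM has 6.55 counts in SK-LMS-1 and 8.05 counts in SK-UT-1.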

Other observations

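The test of poly(A) yield was chosen only after the result was seen and replaced earlier ones, on the histone genes at least 2-fold higher in SK-UT-1 with the whole interval higher (16 of 65) and on the median of 27 other RNAs without a poly(A) tail (-0.19). The reading of the 6 arms lost under a filter was also set after the result, and the other tests were set out before. The genes of this paragraph and the next were chosen after their values were seen. RB1, the retinoblastoma tumour suppressor, stood at 147 CPM in SK-LMS-1 and 8.20 CPM in SK-UT-1, 17.9-fold higher in SK-LMS-1 (13.9 to 23.3, 961 against 66 counts). In hg38 it spans chromosome 13, 48303747 to 48481890, on the plus strand. Most neighbours differed less. LPAR6, which lies within RB1 on the other strand, had 7 counts in SK-LMS-1 and 0 in SK-UT-1, at least 2.87-fold higher, too few to set against RB1. SUCLA2 was 1.57-fold higher in SK-UT-1 (1.23 to 2.0). ITM2B was 2.16-fold higher in SK-LMS-1 (1.92 to 2.43), MED4 1.12-fold (0.919 to 1.37), RCBTB2 1.17-fold (0.723 to 1.88) and FNDC3A 2.34-fold (2.15 to 2.55), and the arm 13q as a whole had a median log2 ratio of 0.36. The line with the lower RB1 had the higher CDKN2A, by 11.9-fold (7.85 to 18.8), and the higher CCNE1, by 4.39-fold (3.35 to 5.84).

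Among receptor genes, EGFR was 4.92-fold higher in SK-LMS-1 (4.57 to 5.31), at 529 against 107 CPM, and IGF1R, the receptor of insulin-like growth factor, 51.2-fold (33.9 to 81.2). The fibrillar collagen genes parted, with COL1A1 14.1-fold higher in SK-LMS-1 (12.8 to 15.6), COL1A2, which encodes its partner chain, at 545 and 467 CPM, and COL3A1 35.5-fold higher in SK-UT-1 (25.7 to 50.7). CDH2, the N-cadherin gene, was 44.6-fold higher in SK-LMS-1 (37.4 to 53.7). Beside AXIN2, the WNT target gene NKD1 was at least 13.6-fold and TCF7 30.4-fold (14.5 to 76.2) higher in SK-UT-1, whereas LEF1, a related transcription factor, was 6.86-fold higher in SK-LMS-1 (3.68 to 13.9). In the interferon group, IFIT1 was 10.7-fold (8.58 to 13.5) and the RNA sensor IFIH1 5.99-fold (4.70 to 7.73) higher in SK-UT-1, while DDX60 and TMEM173, the signalling adaptor STING, were 4.08-fold (3.10 to 5.42) and 4.11-fold (2.63 to 6.64) higher in SK-LMS-1.

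Of the 41 chromosome arms, 25 had medians outside the range of matched random lists. Removing the trend of the ratio with GC content and exon length left 24 of the 25 outside on the same side, which argues against that bias as the main source. With genes 2-fold or more different left out, 19 of the 25 stayed outside on the same side, so those shifts were also present among genes within 2-fold. The filter is no real test of a few strongly different genes, because such genes move the median of an arm little in any case. The filter shrinks any shift of a whole arm and drops many genes, so the loss of the other 6 decides nothing. Differences in DNA copy number between the lines are a candidate explanation, untested here because copy number was not measured.

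The zinc finger family had a median log2 ratio of -0.38 over 494 genes. After subtracting from each gene the median of the other genes on its arm, it was -0.27, outside the random range of -0.11 to 0.10. Shifts of whole arms could thus explain part of the difference and not the whole of it. The subtraction does not remove a shift of a segment within an arm, so position on that scale stays open. After removing the trend with GC content and exon length, the median over 490 genes was -0.43. Without either correction, genes on chromosome 19, where the family is clustered, gave -0.36 (245 genes) and those elsewhere -0.39 (249 genes). A difference in H3K9 methylation between the lines may be involved as a hypothesis, but no chromatin was measured and it stays untested.

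Histone genes of the HIST1 cluster were often silent in SK-UT-1: 12 of 50 had 0 counts there and 0 of 50 in SK-LMS-1, with HIST1H1B at 869 against 0 counts and HIST1H3C at 621 against 0, while 23 of the 38 genes lying between the first and last silent gene had 10 counts or more in SK-UT-1, and the 6 HIST2 genes without same-strand overlap, among them HIST2H3D with only 19.6% unique sequence, were at least 2-fold higher in SK-UT-1 with the whole interval higher. Of 9 other small RNAs without a poly(A) tail and with 100 counts in a library, 7 were higher in SK-LMS-1, RN7SK by 2.15-fold and RPPH1 by only 1.10-fold. MALAT1, a long non-coding RNA outside that set, went the other way, with 17805 counts in SK-LMS-1 and 46182 in SK-UT-1. Over all 27 RNAs of this kind, the 9 included, the median log2 ratio was -0.19, towards SK-UT-1. A yield lower by about 2.15-fold in SK-UT-1 thus stays open for the abundant small RNAs only and was not seen across the whole set. None of the 9 exceeded a log2 ratio of 1.35, against a median of 4.42 for the histone genes at least 2-fold higher in SK-LMS-1. Those genes were picked for being higher, and all 65 histone genes had a median of 0.15. The comparison shows only that a uniform loss of that size would not alone give ratios near 4.42. Furthest towards SK-LMS-1 among the small RNAs without a poly(A) tail and with fewer counts, SNORD3A (81 against 11 counts) had 3.18. RNU6-26P (22 against 1 count) had 4.76 (2.13 to 10.1), or 3.17 with the floor of 3 counts that the histone median uses. Furthest the other way, SCARNA9L (3 against 38 counts) had -3.37 (-5.71 to -1.71). Subtracting arm medians left 43 of the 46 strongly different histone genes in place. Their sizes largely fixed that result, since the medians of 6p and 1q over all measured genes were only 0.39 and -0.68. Shifts of that size could not alone give the larger of these ratios. Shared reads between copies do not account for the 46 histone genes of largely unique sequence. Of these, 65.2% differed by 2-fold or more, against 84.2% of the 19 others, which include 3 pairs of HIST2 genes with the same coordinates and counts. Whether the genes that kept their counts also make polyadenylated transcripts was not examined, and a difference between the lines in control of single HIST1 genes may be involved as an untested hypothesis.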
